A study of Homo sapiens with 44 samples.

How the data were processed

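The samples were HCT116 cells infected with a pooled CRISPR-Cas9 guide library and sorted by reporter fluorescence, per the labels. Guide inserts were amplified from genomic DNA and sequenced, per the labels' protocols. The submitters' processing notes name Bowtie 1.0.1 and the build hg19 without saying how they were used, and how runs and replicates were joined is not given in the sources used here. The deposited signal is, by the authors' normalisation, the reads of each guide per 1000000 reads of its sublibrary (RPM) plus 1. This was read from the values: within sublibrary A and within sublibrary B every column minus 1 sums to 1000000, and the values minus 1 are whole multiples of a single step. The step gave the read totals, and count models were not used. Reads came from PCR products, and ceilings for guides without a read cover counting error only. All 12 columns were matched to the 6 groups, with 0 unmatched. The EGFP reporter columns carry an E in their names, and the columns with the other letter were taken as the miR-19 reporter, which is an inference from the names. The column codes of the reporter screens appear in no label, so their replicate numbers are unknown, and the columns are named here by depth as deeper and shallower. Sublibraries A and B hold 63777 and 56125 guides. Of the gene names 24 look like dates and were left as given.

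All choices of test, filter, gene list and named gene were made before the data were examined, except those said to be added. Guides were kept where their mean over the unsorted columns of their table was at least 0.1 of the mean value per guide, which kept 111254 guides in the reporter table and 112079 in the ANKRD52 KO table. A pseudocount of 1.77, 0.1 of the mean value per guide of 17.7, was added before taking log2. Values were averaged over the guides of a gene, genes needed at least 3 guides, and each column was centred on its median over genes. Before centring the median log2 ratio was -0.07 with the miR-19 reporter, -0.18 with the EGFP reporter, 0.11 for their difference, -0.07 for unsorted cells and 0.01 in the ANKRD52 KO line, and changes are given relative to these. Non-targeting guides were grouped into seeded random sets of 6, 3 per sublibrary, and treated as genes.

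Linear models were fitted in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with a variance trend, and tests were two-sided. Each of the 5 comparisons used only its own groups, and the difference between reporters used all 8 columns of that table. Benjamini-Hochberg adjustment ran over genes and control sets together, with a threshold of 0.05. With 2 residual degrees of freedom (4 for the difference) the prior decides most of the variance, and for the unsorted and ANKRD52 KO comparisons the estimated prior degrees of freedom were infinite, so very small p-values there rest on the fitted trend. Gene lists were tested in camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 19 lists per comparison. The form with an estimated correlation rests on the residual degrees of freedom, so a list could hardly pass there. The preset form assumes its correlation and does not check it. The guide-rank test combined the ranks of a gene's guides among the top 0.25 of all guides by robust rank aggregation, against 1000000 random draws. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.

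The genes named are the measured members of the microRNA biogenesis and Argonaute lists, ANKRD52, PPP6C, CSNK1A1 and the miR-19 loci. To these were added, per comparison, at most 12 genes higher and 4 lower with the smallest p among those past the threshold with one sign in both columns, and up to 4 members per list. Any other gene was chosen after its values were seen. For gene order, names were matched to an annotation of GRCh38.p14, which served only for names and order since the deposited values rest on hg19, and 19452 of 20670 names matched (94.1%). Windows of 31 genes were compared with 1000 permuted orders, and medians of gene sets with 10000 random lists. The gene order scans and the lists of translation, growth and RNA-binding genes in the closing section were not among the choices fixed in advance.

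The fits were tested on simulated data made by reassigning the real guides to genes at random and multiplying 200 genes in the first group by known folds. With a change of 8-fold limma recovered 28 of 66 genes with the miR-19 reporter, 27 of 66 with the EGFP reporter, 6 of 66 for the difference, 18 of 66 for unsorted cells and 66 of 66 in the ANKRD52 KO line. With a change of 4-fold it recovered 7, 9, 0, 1 and 65 of 67 genes in the same order, and with 2-fold 0, 0, 0, 0 and 19 of 67. Among the unchanged genes 7, 9, 3, 2 and 67 were called, out of 19817 genes in the reporter fits and 19837 in the ANKRD52 KO fit. As a share of all calls in the same fit, these calls were above the nominal rate in every fit, including the reporter fits, where the counts are small. Reassigned guides kept any real change of their own, so genes taken as unchanged could hold changed guides. These counts are therefore not a pure error rate. The last count was the largest, and the cause was not established. The reassignment without planted changes was therefore drawn 20 times, with and without the most extreme guide of each gene. Alternatives changed the pseudocount, guide filter, centring, gene summary, minimum number of guides, sublibrary, pairing, trend, test and the columns used, and their effects are given in the closing section. Sequencing runs per sample were not used here.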

Results

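Pooled CRISPR-Cas9 knockout screens with the GeCKO guide library were sequenced from HCT116 cells, a human colorectal carcinoma line. The cells carried a fluorescent EGFP reporter or an EGFP reporter named for miR-19, a microRNA of the miR-17-92 cluster. Cells were sorted by reporter fluorescence, and the integrated guides were counted in the sorted fraction and in unsorted cells. A guide more frequent in the bright fraction points to a gene whose loss goes with a brighter reporter. A second kind of screen used a line with a knockout of ANKRD52, a regulatory subunit of protein phosphatase 6, and collected the dim fraction. The labels list 44 samples in 6 groups, and the deposited values hold 12 columns, with 2 columns per group. Each column covers 119902 guides against 20670 gene and microRNA names, with 2000 non-targeting guides.

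Read totals were recovered from the deposited values. The miR-19 reporter columns held 37.9 M and 24.3 M reads in the bright fraction and 48.9 M and 25.8 M in unsorted cells. The EGFP reporter columns held 66.0 M and 24.0 M reads in the bright fraction and 60.1 M and 24.6 M in unsorted cells. The ANKRD52 KO columns held 39.1 M and 37.4 M reads in the dim fraction and 32.0 M and 34.2 M in unsorted cells. Guides without a read made up 36.8% and 39.7% of the library in the shallower bright columns of the miR-19 and EGFP reporters, and 8.6% and 10.6% in the deeper ones. In the ANKRD52 KO line this share was 6.7% and 8.4% in the dim columns and 7.6% and 9.7% in the unsorted columns. In the shallower miR-19 bright column a single guide took 13.33% of the reads of sublibrary A, and 10 guides took 32.9%. Guide levels are given as RPM, reads per 1000000 reads of a sublibrary. A guide with no read could hold at most 0.0714 to 0.312 RPM, depending on the column and sublibrary, from a limit of 3 counts that covers counting error only. Replicate columns correlated across genes with r = 0.504 in the miR-19 bright fraction, 0.412 in the EGFP bright fraction and 0.671 in the ANKRD52 KO dim fraction. Across unsorted cells r was 0.322, 0.347 and 0.607 in the same order, and genes are not independent replicates.

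The first comparison asked which guides are more frequent in the bright fraction with the reporter named for miR-19. Guides against DROSHA, the nuclease that releases microRNA precursors in the nucleus, averaged 141 ± 20.6 RPM in the bright fraction and 10.2 ± 3.65 in unsorted cells (SD, n = 2). The log2 ratio of DROSHA was 3.61 ± 0.53 (SE; limma adjusted p = 6.4e-05). XRN1, the 5'-3' exonuclease that degrades decapped RNA, had 389 ± 19.2 against 16.5 ± 6.47 RPM and a log2 ratio of 3.99 ± 0.61 (limma adjusted p = 7.1e-05). ANKRD52 had 180 ± 3.76 against 10.3 ± 6.30 RPM and a log2 ratio of 3.46 ± 0.55 (limma adjusted p = 1.6e-04). Guides against hsa-mir-19b-1, a gene that encodes miR-19b itself, had 364 ± 167 against 28.6 ± 21.4 RPM and a log2 ratio of 3.26 ± 0.66 (limma adjusted p = 0.022). These 4 genes were higher in both columns, and they were the only ones of 19817 tested that passed an adjusted p of 0.05. That count depended on the processing: 0 genes passed with the median over guides and 1 without the most extreme guide. It also changed when single columns were left out, as given in the closing section. No gene was lower, while at an unadjusted p under 0.05 limma counted 500 higher and 453 lower, and the guide-rank test called 3 higher and 0 lower. DROSHA, XRN1 and ANKRD52 passed the guide-rank test, each with an adjusted p of 0.013, whereas hsa-mir-19b-1 missed it at 0.071.

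Other genes of the microRNA pathway were higher with the miR-19 reporter without passing the threshold over all genes. The log2 ratio of DGCR8, the partner of DROSHA, was 2.29 ± 0.51 (limma adjusted p = 0.108). PPP6C, the catalytic subunit that ANKRD52 joins, had 1.96 ± 0.53, the export factor XPO5 1.85 ± 0.52, the slicer AGO2 1.82 ± 0.50 and DICER1 1.50 ± 0.52 (limma adjusted p = 0.607, 0.757, 0.709 and 0.893). All of these had the same sign in both columns. The second miR-19 locus of the same cluster, hsa-mir-19a, had 1.36 ± 0.55, and the copy on another chromosome, hsa-mir-19b-2, had -0.84 ± 0.54 with opposite signs in its columns. CSNK1A1, which encodes casein kinase 1 alpha, had -0.59 ± 0.51. TNRC6A, TNRC6B and TNRC6C, the scaffold proteins that Argonaute recruits, had -0.77, 0.63 and 0.49, and AGO1, AGO3 and AGO4 had 0.21, 0.40 and 0.15. TARBP2 and PRKRA, which bind Dicer, had 0.38 and 0.14, DDX5 and DDX17, which assist Drosha, had 0.60 and 0.38, and RAN had 0.64. The cap-binding genes NCBP1 and NCBP2 had 0.39 and 0.11, and SRRT had -0.48.

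Among the fixed gene lists, microRNA biogenesis shifted up with the miR-19 reporter (median log2 ratio 0.50 over 12 genes, camera adjusted p = 5.7e-07; adjusted p = 0.416 with an estimated correlation). Of its members 1 passed over all genes, and 4 passed when adjusted over the list alone, namely DROSHA, DGCR8, XPO5 and DICER1. Decapping and 5'-3' decay shifted up (median 0.48 over 11 genes, camera adjusted p = 1.0e-04; adjusted p = 0.416 with an estimated correlation), with 1 member past the threshold over all genes and 2 adjusted over the list alone, XRN1 and the helicase DDX6. The ANKRD52 and protein phosphatase 6 list shifted up (median 0.25 over 7 genes, camera adjusted p = 0.0035; adjusted p = 0.730 with an estimated correlation), with ANKRD52 past over all genes and ANKRD52 and PPP6C adjusted over the list alone. The ANKRD52 and casein kinase lists were chosen also with knowledge of the published study on these samples and are not independent evidence. Neither are the microRNA biogenesis and Argonaute lists. The Argonaute and TNRC6 list (AGO2 adjusted over the list alone) and SWI/SNF had camera adjusted p = 0.167. The miR-17-92 list and 3' tailing and microRNA turnover had 0.276, with hsa-mir-19b-1 past over all genes and 3 higher and 2 lower microRNA genes adjusted over the miR-17-92 list alone. DNA methylation and histone deacetylation had 0.444. The deadenylases, the Argonaute loading chaperones, HUSH and heterochromatin silencing, the cytosolic ribosomal proteins, the proteasome and the growth control list all had 0.607. Nonsense-mediated decay, Mediator and the olfactory receptors had 0.740, and the casein kinase 1 family and Polycomb had 0.876. The casein kinase 1 family had a median of 0.12 beside a mean of -0.03 and a downward test.

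The same comparison with the EGFP reporter used the reporter whose label names no miR-19. A single gene passed the threshold there. Guides against SLTM, a chromatin-associated RNA-binding protein, had 112 ± 1.76 RPM in the bright fraction and 11.8 ± 1.33 in unsorted cells, a log2 ratio of 2.88 ± 0.54 (n = 2, limma adjusted p = 0.0044). SLTM rested on 3 guides and missed the guide-rank test (adjusted p = 0.818). No gene was lower by limma, which counted 533 higher and 499 lower at an unadjusted p under 0.05, and the guide-rank test called 0 in either direction. The genes past the threshold with the miR-19 reporter had negative values here: the log2 ratio of DROSHA was -0.84 ± 0.54, of ANKRD52 -0.76 ± 0.54, of hsa-mir-19b-1 -0.78 ± 0.54 and of XRN1 -0.49 ± 0.55, with opposite signs in the columns of XRN1. DDX5 had 1.74 ± 0.53 and hsa-mir-19a had 1.68 ± 0.53 (limma adjusted p = 0.779 for both), and each passed when adjusted over its list alone. No list passed in camera, with adjusted p from 0.237 to 0.889, and in 2 lists the median and the test differed in sign.

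The difference between the reporters was tested directly, as the bright enrichment with the miR-19 reporter minus that with the EGFP reporter over 8 columns. XRN1 differed by a log2 value of 4.49 ± 0.75 and DROSHA by 4.44 ± 0.75 (limma adjusted p = 4.5e-04 for both). ANKRD52 differed by 4.22 ± 0.75 (limma adjusted p = 0.0012) and hsa-mir-19b-1 by 4.05 ± 0.74 (limma adjusted p = 0.0022). These were the 4 genes past the threshold, all higher, and all 4 also passed the guide-rank test. Limma called 0 genes lower, with 487 higher and 489 lower at an unadjusted p under 0.05, and the guide-rank test called 0 lower. Without the most extreme guide of each gene the 4 differences were 3.38 to 3.94, and none of them passed (limma adjusted p = 0.154 to 1.00). The difference was 2.44 ± 0.74 for DGCR8, 2.04 ± 0.74 for DICER1, 1.97 ± 0.76 for AGO2, 1.74 ± 0.73 for XPO5 and 1.40 ± 0.74 for PPP6C, and these did not pass (limma adjusted p = 0.718 for DGCR8 and 0.999 for the others). For hsa-mir-19a the difference was -0.32 ± 0.79, which rests in part on a low level of 3.04 RPM in unsorted EGFP reporter cells. MicroRNA biogenesis (camera adjusted p = 0.0062; adjusted p = 0.245 with an estimated correlation) and decapping (camera adjusted p = 0.0092; adjusted p = 0.245 with an estimated correlation) were the lists that shifted up. Adjusted over the list alone, 3 biogenesis genes passed (DROSHA, DGCR8 and DICER1) and 1 decapping gene (XRN1), with 1 of each past over all genes. The Argonaute list and the ANKRD52 list missed the threshold at 0.0834, the other lists reached up to 0.954, and in 1 list, nonsense-mediated decay, the median and the test differed in sign.

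**Figure D1:**
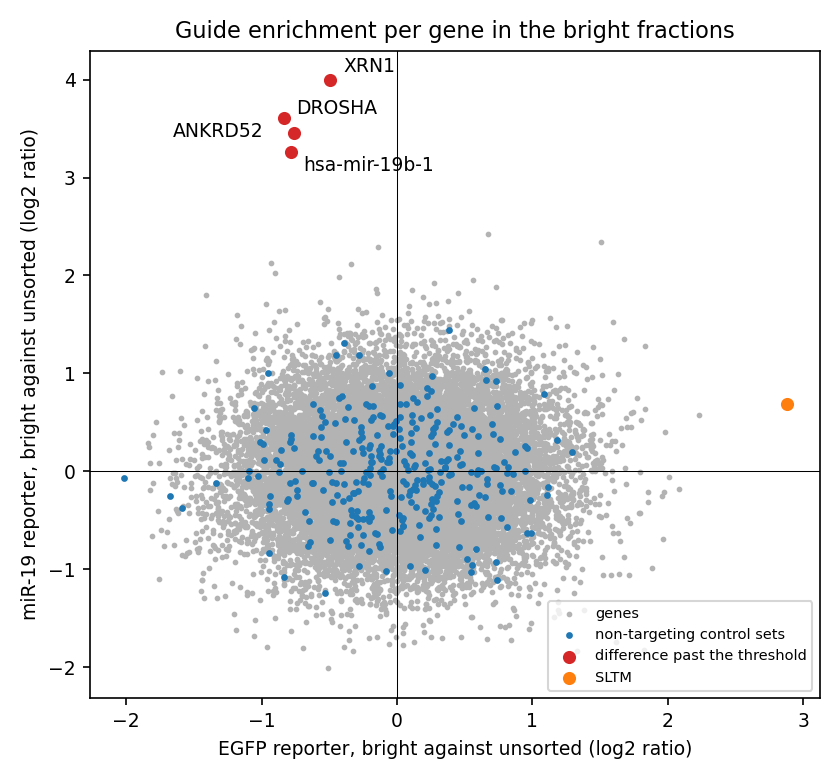
Log2 ratio of bright against unsorted guides per gene with the EGFP reporter (horizontal axis) and the miR-19 reporter (vertical axis), for genes (grey), non-targeting control sets (blue), genes past the threshold for the difference (red) and SLTM (orange). XRN1, DROSHA, ANKRD52 and hsa-mir-19b-1 lie at 3.26 to 3.99 on the vertical axis and below 0 on the horizontal axis, and SLTM lies at 2.88 on the horizontal axis.

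**Figure D2:**
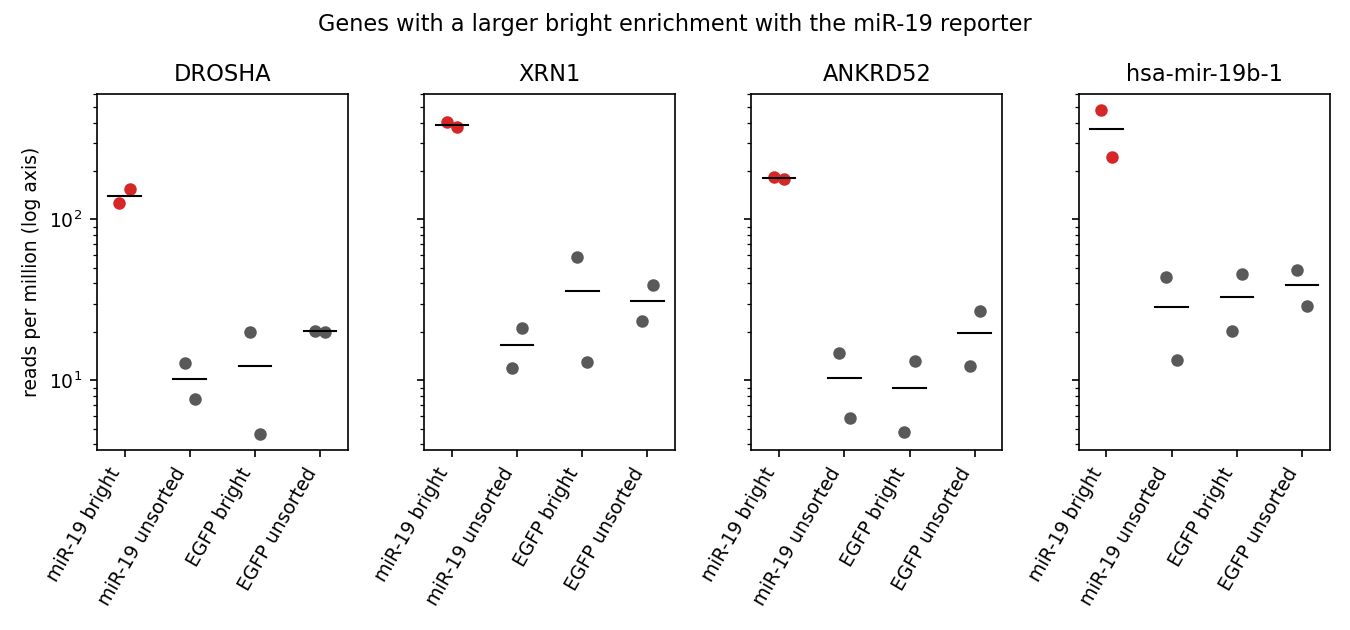
Mean RPM over the guides of each gene, on a log axis, in each of the 8 columns (points) with the mean of each group (lines). DROSHA averaged 141 RPM, XRN1 389, ANKRD52 180 and hsa-mir-19b-1 364 in the bright fraction with the miR-19 reporter.

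The unsorted populations of the reporters were compared as a background. Among the named genes hsa-mir-19a had the smallest p, with a log2 ratio of 1.73 ± 0.57 (n = 2, limma adjusted p = 0.832), and it passed when adjusted over its list alone. Guides against DROSHA were lower in the unsorted miR-19 reporter cells by a log2 ratio of -1.09 ± 0.55 (limma adjusted p = 0.968). Limma called 0 genes, with 487 higher and 534 lower at an unadjusted p under 0.05, and the guide-rank test called 0. No list passed in camera (adjusted p = 0.288 to 0.991), and in 6 lists the median and the test differed in sign. Guides against cytosolic ribosomal proteins, which proliferating cells need, lay below the non-targeting sets in all 6 unsorted columns, with a median log2 value of -0.51 to -0.80 over 74 genes. The proteasome, also needed for growth, lay at -0.46 to 0.01 over 39 genes, with -0.05 and 0.01 in the shallower columns, and Mediator lay at -0.13 to 0.13 over 32 genes. Olfactory receptor genes, which this line has no known use for, lay at 0.09 to 0.27. The SD of the control sets in these columns was 0.49 to 0.71. No sample of the library before infection is among the labels, so loss of guides in culture could not be told apart from their share in the library.

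The screen in the ANKRD52 KO line compared the dim fraction with unsorted cells. Guides against PRDM4, a zinc finger transcription factor, averaged 545 ± 72.4 RPM in the dim fraction and 24.0 ± 5.49 in unsorted cells (SD, n = 2), a log2 ratio of 3.79 ± 0.14 (limma adjusted p = 1.5e-146). LATS2, a kinase of the Hippo growth control pathway, had 350 ± 77.1 against 40.3 ± 16.5 RPM and a log2 ratio of 2.78 ± 0.16 (limma adjusted p = 4.0e-65). CELF1, MBNL1 and IGF2BP3, which encode RNA-binding proteins, had 2.17 ± 0.25, 2.16 ± 0.26 and 1.75 ± 0.20 (limma adjusted p = 4.0e-14, 1.3e-13 and 1.8e-14). FKBPL, an immunophilin-like protein, had 2.25 ± 0.32, the growth kinase MTOR 1.96 ± 0.31, and the translation initiation genes EIF3H and EIF3M 1.80 ± 0.26 and 1.73 ± 0.31. CSNK1A1 was higher in the dim fraction, with 54.9 ± 5.26 against 18.0 ± 11.9 RPM and a log2 ratio of 1.33 ± 0.25 (limma adjusted p = 2.1e-04, guide-rank adjusted p = 0.020). The per-replicate ratios of CSNK1A1 were 2.07 and 0.59. CSNK1A1 missed the threshold without the variance trend (adjusted p = 0.0558), with the median over guides (0.537) and without its most extreme guide (0.349).

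In that line limma called 73 genes higher and 30 lower among 19837, with 1056 and 904 at an unadjusted p under 0.05, and the guide-rank test called 14 higher and 0 lower. The limma counts changed widely when a single column was left out, as given in the closing section. When guides were reassigned to genes at random in 20 draws, limma called a median of 9.5 genes higher and 6 lower, with a maximum of 32 and 19. The count of calls in this line therefore includes calls that random sets of guides also give, and the SE reflects spread between columns and not between guides. Without the variance trend PRDM4 kept 3.79 ± 0.30 (limma adjusted p = 5.4e-14) and LATS2 2.78 ± 0.31 (limma adjusted p = 1.4e-08). Without the most extreme guide of each gene 12 of the 73 genes still passed, against at most 1 after reassignment, and the median log2 ratio of the 73 moved from 1.24 to 1.02. PRDM4, LATS2, FKBPL, CELF1, MBNL1, MTOR, EIF3H and IGF2BP3 passed both without that guide and in the guide-rank test, which makes 8 genes. CST1, a secreted protease inhibitor, had 1.59 ± 0.26, RBBP9 1.27 ± 0.21 and MRGBP 1.35 ± 0.25, all on chromosome 20, and MRGBP missed the threshold without its most extreme guide. Among genes lower in the dim fraction TUBA1B had -2.46 ± 0.31, DMRT1 -1.61 ± 0.28, SSTR5 -1.12 ± 0.22 and hsa-mir-592 -1.21 ± 0.25, and 0 of the 30 genes passed without the most extreme guide, where their median log2 ratio went from -1.20 to -0.95.

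Guides against ANKRD52 itself had a log2 ratio of 0.21 ± 0.29 in the dim fraction (n = 2, limma adjusted p = 0.884), which does not check the knockout because guide counts do not measure it. Other genes with high ratios in the bright fraction did not pass here, with DROSHA at -0.54 ± 0.35, DGCR8 at 0.21 ± 0.35, AGO2 at -0.49 ± 0.37, PPP6C at -0.29 ± 0.29 and hsa-mir-19b-1 at -0.13 ± 0.28. XRN1 had -1.03 ± 0.30 (limma adjusted p = 0.0935), past the threshold when adjusted over its list alone, as were CNOT7, ZSWIM8 and the proteasome gene PSMB4, all lower. Growth control and tumour suppressor genes shifted up (median 0.45 over 15 genes, camera adjusted p = 2.0e-10; adjusted p = 0.233 with an estimated correlation). Of that list LATS2 and KEAP1 passed over all genes, and NF2 joined them when adjusted over the list alone. Olfactory receptors shifted down by a median of -0.10 over 360 genes (camera adjusted p = 0.028; adjusted p = 0.233 with an estimated correlation). The casein kinase 1 family, with CSNK1A1 as its only member past the threshold both over all genes and over the list alone, had a camera adjusted p of 0.907. The other lists had camera adjusted p from 0.907 to 0.963, and in 4 lists the median and the test differed in sign.

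**Figure D3:**
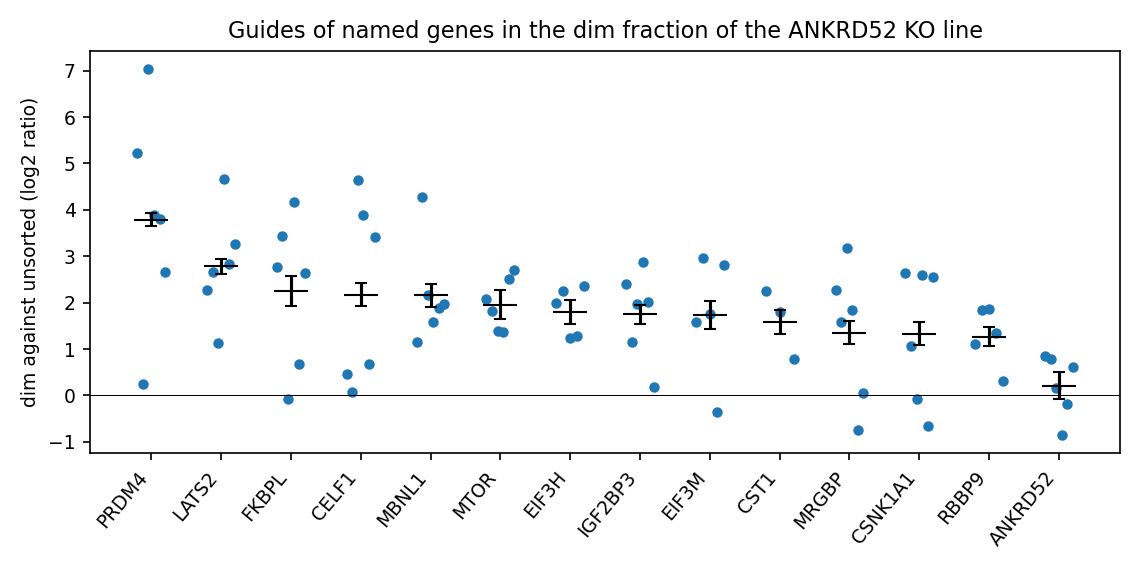
Log2 ratio of dim against unsorted reads in the ANKRD52 KO line for each guide of the named genes (points, mean of 2 replicates) and for the gene (bars, value and SE). PRDM4 reached 3.79 and LATS2 2.78, and ANKRD52 itself 0.21.

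Genes were also set in the order in which they lie on the chromosomes, and running means of the log2 ratio over 31 genes were compared with 1000 permuted orders. In the dim fraction of the ANKRD52 KO line 137 windows passed, all on chromosome 20, and the highest, from XRN2 to NINL, had a mean of 0.73 against a permuted maximum of 0.35 (permutation p = 0.000999, the smallest the permutations allow, and 0.00999 adjusted over 10 scans). Of 528 genes on chromosome 20, 22 were called higher, against 48 of 18400 elsewhere (one-sided Fisher's exact test, p = 1.0e-17, not adjusted over chromosomes). That p treats the genes as independent, while neighbouring genes shifted together here, so it is too small. On the short arm, from C20orf96 to GGTLC1, 135 of 159 genes had a positive log2 ratio. The 139 genes of that stretch that did not pass the threshold had a median of 0.37, with replicate medians of 0.38 and 0.40. In a scan without the 103 called genes 111 windows passed, all on chromosome 20, the highest with a mean of 0.54 against a permuted maximum of 0.33 (permutation p = 0.000999, the smallest the permutations allow). After ZNF337, on the long arm, the median over 351 genes was 0.04, above 98.9% of random lists. The stretch did not stand out in the other comparisons, with medians from -0.05 to 0.05.

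With the miR-19 reporter 18 windows passed in the bright fraction, all on chromosome 13 (permutation p = 0.00200, 0.00999 adjusted over 10 scans). The highest ran from KLHL1 to hsa-mir-19a with a mean of 0.52, and hsa-mir-19b-1 and hsa-mir-92a-1, whose names were not matched, were not in the scan. Of the 29 genes from KLHL1 to the miR-17-92 cluster 27 were higher, with a median of 0.48, and of the 89 genes after the cluster 67 were higher, with a median of 0.32. The set from KLHL1 was bounded from that highest window. Its values are therefore no support beyond the scan, also in the difference between the reporters, which reuses them. The medians of the same sets with the EGFP reporter were 0.08 and 0.04, and their medians for the difference between the reporters were 0.51 and 0.43. In the scan of that difference the highest window, also on chromosome 13, did not pass (permutation p = 0.0879). Within the cluster hsa-mir-92a-1 had 1.58 ± 0.58 and hsa-mir-18a 0.48 ± 0.54 with the miR-19 reporter. No window passed in the EGFP bright fraction or in the unsorted comparison, in either direction.

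**Figure D4:**
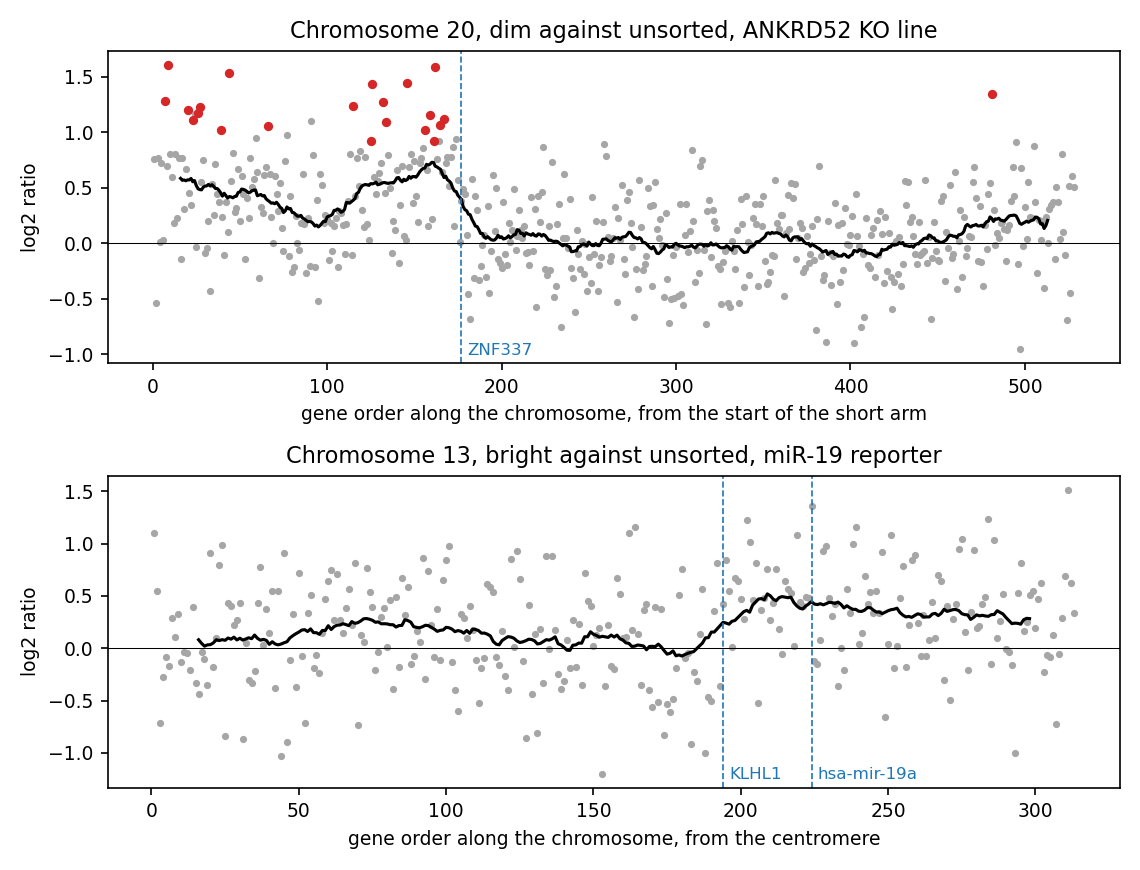
Log2 ratio per gene (points, red where called higher) and running mean over 31 genes (line) in gene order along chromosome 20 for the dim fraction of the ANKRD52 KO line, and along chromosome 13 for the bright fraction with the miR-19 reporter. The running mean reaches 0.73 before ZNF337 and 0.52 between KLHL1 and hsa-mir-19a.

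Non-targeting guides gave the background of the gene tests. Grouped at random into sets of 6, 311 control sets were tested in each of the reporter comparisons and 317 in the ANKRD52 KO line, and limma called 0 of them in any comparison. At an unadjusted p under 0.05 limma counted 12 sets with the miR-19 reporter, 12 with the EGFP reporter, 12 for the difference, 15 for unsorted cells and 23 in the ANKRD52 KO line, which is 7.26% of the sets there. The SD of the control sets' log2 values was 0.48 with the miR-19 reporter, 0.53 with the EGFP reporter and 0.34 in the ANKRD52 KO line.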

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

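The tests without each gene's most extreme guide, with each sublibrary centred on its own, of the size of the difference that remains, and the use of the fit without the shallower miR-19 bright column as a test were chosen only after results had been seen. Guides against DROSHA, XRN1, ANKRD52 and hsa-mir-19b-1 were enriched in the bright fraction with the miR-19 reporter, and had negative log2 ratios with the EGFP reporter. The tested difference between the reporters was 4.44 ± 0.75 for DROSHA, 4.49 ± 0.75 for XRN1, 4.22 ± 0.75 for ANKRD52 and 4.05 ± 0.74 for hsa-mir-19b-1 on the log2 scale (limma adjusted p = 4.5e-04, 4.5e-04, 0.0012 and 0.0022).

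A single expanded guide per gene predicted, before its test, that at most 1 of the 4 genes would pass without the most extreme guide. Of the 4 genes 0 passed, so by this test alone a single guide stays open as a part of these calls. The differences went to 3.94 ± 0.82 for DROSHA, 3.79 ± 0.87 for XRN1, 3.88 ± 0.81 for ANKRD52 and 3.38 ± 0.89 for hsa-mir-19b-1, and the calls ended with values lower by less than 1 SE, larger SEs, and prior degrees of freedom of limma that went from 90.3 to 44.5, whose shares were not tested. The lowest remaining difference was 3.38, so other guides also carried the difference, in a test set after that outcome was known. It decides little about the calls, because log2 values were averaged over 4 to 6 guides per gene. Calls from randomly reassigned guides, at most 1 per draw, kept 83.9% of their summed log2 difference. Guides were also counted that lay above the 95th percentile of non-targeting guides in both column pairs of the miR-19 reporter. These were 3 of 5 for DROSHA, 4 of 6 for XRN1 and 3 of 6 for ANKRD52. The counts, weighed after the calls were known, argue against a single guide behind the bright enrichment of these genes. For hsa-mir-19b-1 the count was 1 of 4, and a single guide stays open there. A few guides taking a large share of the reads of sublibrary A in the shallower miR-19 bright column are argued against, since without that column 4 of the 4 genes still passed, with limma adjusted p of 0.0114 to 0.0121 and differences such as 4.35 ± 0.86 for XRN1 and 4.28 ± 0.87 for ANKRD52. Centring each sublibrary on its own decides nothing for genes with guides in both, since the median change over all genes was 0.0134, and it moved the median of the 4 genes by 0.0503 and hsa-mir-19b-1, with guides in sublibrary A only, from 4.05 to 4.41, and the shallower EGFP bright column, where the top guide took 7.33% of those reads, was not decided: without it ANKRD52 (4.78 ± 0.82) and hsa-mir-19b-1 (4.42 ± 0.83) passed, while DROSHA (3.66 ± 0.80) and XRN1 (3.74 ± 0.83) missed the threshold (limma adjusted p = 0.0881 for both). A response of the reporter to miR-19 and a difference between the reporter cell populations unrelated to miR-19 also stay open, untested.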

How the results depend on the processing

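The tests without the most extreme guide of each gene, with each sublibrary centred on its own, with both shallower columns left out at once (log2 ratios only, no test) and without chromosome 20 were chosen after seeing the data. No named gene reversed a call under any alternative run. Among values for named genes 100 lost the threshold and 15 gained it, 47 moved with their sign kept and 16 with a change of sign, and 208 others changed sign without a change of call.

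With the miR-19 reporter 4 genes were higher. The count was 11 with a pseudocount equal to the mean value per guide, 9 with the log2 of the mean over guides, 0 with the median over guides, 1 with sublibrary B only and 1 without the most extreme guide. The 4 genes were among the 11, and 2 of them among the 9, while the 1 call with sublibrary B only was none of them. All 4 kept guides of hsa-mir-19b-1 lie in sublibrary A, so sublibrary B only could not call it. Leaving out each column in turn gave 0 to 35 higher and 0 to 37 lower. The 0 higher came without the shallower unsorted column, the 35 and 37 without the deeper one, where 2 of the 4 were among the 72 calls, and without the deeper bright column 7 were higher and 1 lower. With the EGFP reporter the 1 gene, SLTM, was lost (0 higher) with the guide filter at 0.5, the median over guides, at least 5 guides, sublibrary A only, sublibrary B only, the guide-rank test and without the most extreme guide. SLTM has 3 guides, so the minimum of 5 removes it by construction. Fits to a single sublibrary needed 2 guides per gene, so SLTM could be tested in at most 1 of them. Leaving out each column gave 0 to 2 higher and 0 to 1 lower, with 2 higher without the deeper bright column, 0 without any other, and 1 lower without the deeper unsorted column.

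For the difference between the reporters 4 genes were higher. The count was 0 with the median over guides, 2 with sublibrary A only, 0 with sublibrary B only and 0 without the most extreme guide. With sublibrary B only hsa-mir-19b-1 could not be called, since it has no kept guide there. Against 0 lower, 2 were lower with a pseudocount of 0.02 of the mean value per guide and 1 without a guide filter. Leaving out each column gave 2 to 6 higher and 0 to 3 lower. There were 2 higher without the shallower unsorted miR-19 column and without either EGFP bright column or the shallower EGFP unsorted column. There were 3 lower without the deeper miR-19 unsorted or the deeper EGFP bright column, 2 without the deeper miR-19 bright column and 1 without the deeper EGFP unsorted column. For unsorted cells 1 gene was higher with the log2 of the mean over guides. Leaving out each column there gave 0 to 7 higher and 0 to 4 lower, with 7 and 4 without the deeper miR-19 column and 1 higher without the deeper EGFP column.

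In the ANKRD52 KO line 73 genes were higher and 30 lower. The higher and lower counts were 118 and 48 with a pseudocount equal to the mean value per guide, 45 and 18 with 0.02 of it, 23 and 3 with the guide filter at 0.5, and 23 and 7 with the median over guides. They were 182 and 79 with the log2 of the mean, 24 and 6 with sublibrary B only, 31 and 9 without the trend, 14 and 0 with the guide-rank test and 12 and 0 without the most extreme guide. With at least 5 guides 18 were lower. Leaving out each column gave 12 to 126 higher and 7 to 38 lower. Without dim replicate 1 there were 12 higher and 9 lower, without dim replicate 2 14 and 7, without unsorted replicate 1 126 higher, and without unsorted replicate 2 10 lower. PRDM4 and LATS2 passed under every alternative with a test. CSNK1A1 went to 0.65 ± 0.27 without unsorted replicate 1 (limma adjusted p = 0.266) and to 2.01 ± 0.30 without unsorted replicate 2, and missed the threshold without dim replicate 1 (0.146) and dim replicate 2 (0.0520). Control sets past the threshold were 1 with a pseudocount equal to the mean, 2 without a guide filter and 2 with the log2 of the mean. Without chromosome 20, 51 genes were higher.

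With an estimated correlation 0 lists passed in place of 3 with the miR-19 reporter, 2 for the difference and 2 in the ANKRD52 KO line. With the replicate block 7 genes were higher with the miR-19 reporter, all 4 among them, 2 were lower for the difference, and 69 were higher and 28 lower in the ANKRD52 KO line. Within a reporter or line, sorted and unsorted columns with one code did not deviate together (correlations of -0.02, 0.03 and -0.00038), and the pairing was not checked across the reporters. No block could be fitted for the unsorted comparison, which left no residual degrees of freedom. Where a column was left out, the lone column was assumed to vary like the other group. The cause of these changes was not tested where none is given.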

Other observations

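The tests of the lists of translation, growth and RNA-binding genes, those without the most extreme guide, the gene order scan without called genes, the comparison of the genes that stay with random reassignment, and that of the genes after the miR-17-92 cluster were chosen only after results had been seen. These were 7 lists built around genes that had passed in the dim fraction of the ANKRD52 KO line, so only their other members bear on a family, and their positions among random lists are not adjusted for the 7 lists. EIF3H and EIF3M, subunits of the initiation factor eIF3, had log2 ratios of 1.80 ± 0.26 and 1.73 ± 0.31, and the other 9 eIF3 genes, none past the threshold, had a median of 0.31, above 98.4% of random lists. EIF4G1, the scaffold of the cap-binding complex, had 1.24 ± 0.32, and the other 5 genes of that complex and its regulators had a median of 0.37, above 97.1% of random lists. MTOR and its partner RPTOR had 1.96 ± 0.31 and 1.24 ± 0.29, while the other 9 genes of mTOR complex 1 and its activators had a median of 0.01, above 54.0% of random lists. The median of the TSC complex, which restrains mTOR, was 0.07 over 3 genes. The cytosolic ribosomal proteins, a list fixed in advance, did not pass, with 0 of 69 genes past the threshold, a median of -0.00 and a camera adjusted p of 0.931.

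CELF1 at 2.17 and MBNL1 at 2.16 are RNA-binding proteins of related function, and the other 7 members of the CELF and MBNL families, none past the threshold, had a median of 0.36, above 98.6% of random lists. In the IGF2BP family IGF2BP3 had 1.75, whereas IGF2BP1 had -0.39 and IGF2BP2 -0.00. LATS2 had 2.78, and the other 7 genes of the Hippo kinase cascade had a median of -0.19, above 12.7% of random lists, with NF2 at 0.86 and LATS1 at -0.19.

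The 73 genes higher in the dim fraction of the ANKRD52 KO line were weighed as a set. A single expanded guide per gene remains open for most of them, since 12 still passed without the most extreme guide, although the median log2 ratio of the 73 went only from 1.24 to 1.02, with 81.5% of their summed log2 ratio left against 66.6% for calls from randomly reassigned guides. For those 12 it is argued against, because random reassignment of guides left at most 1. A change of fluorescence without miR-19 was predicted to lower these guides in the EGFP bright fraction. Their median there lay above 23.6% of random lists, outside the lowest 5% set for it. That does not decide the question, since the labels of those cells name no ANKRD52 knockout and no dim fraction. How far guides that dim the reporter would fall in that bright fraction was not tested. Cas9 cleavage acting through the chromosome remains open for the 21 genes on the short arm of chromosome 20, since a scan without called genes still reached a mean of 0.54 there (permutation p = 0.000999, the smallest they can give), while the median of 0.37 over genes that did not pass decides nothing because the stretch was bounded from the first scan, and whether the reporter lies on that arm and could be lost with it was not tested.

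Neighbouring genes on chromosome 13 were higher in the bright fraction with the miR-19 reporter. Cleavage between the centromere and the miR-17-92 cluster might act by removing the cluster with the rest of the arm, and the genes before KLHL1 had a median of 0.11, above 98.8% of random lists, which leaves it open for them. The same genes had 0.07 with the EGFP reporter and 0.07 for the difference between the reporters (above 87.8% and 85.4% of random lists), so a shift limited to the miR-19 reporter was not shown. The genes after the cluster had a median of 0.32, above all random lists. Their position lies outside this explanation, which therefore does not account for them, and other effects of cleavage on the chromosome were not tested. The microRNA genes of the cluster alone are argued against as carriers of the window, since 12 windows passed with none of them in the scan (permutation p = 0.0110), after removal of hsa-mir-18a and hsa-mir-19a, the only members it had held.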
